A study of Mus musculus with 24 samples.

How the data were processed

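RNA from the medial frontal cortex of mice on the C57BL/6J background was profiled at postnatal day 28. Control mice carried Emx1-cre, a transgene that directs recombination in the dorsal forebrain, in excitatory cortical neurons and glia of the Emx1 lineage. The other genotype came from crossing Emx1-cre mice with a conditional Dnmt3l knock-in line and is called Dnmt3l below. Each of the 4 groups (genotype by sex) held 3 samples, and each sample gave a ribosomal RNA-depleted library and a small RNA library, 12 of each kind. Per the labels' protocols, RNA was extracted with TRIzol or an RNeasy kit, 1 μg with a RNA integrity number above 6.5 went into each library, and the kit marked the second strand with dUTP. The labels number the samples 1 to 3 within each group without saying whether each came from a separate animal, so the p-values measure the spread between these samples, which may be partly technical.

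The submitters' processing notes name bcl2fastq 2.17.1.14, cutadapt 1.9.1, HISAT2 2.0.1, HTSeq 0.6.1, DESeq2, bedtools 2.17.0 and the mouse build GRCm38, with no role or order. Which program counted each kind of RNA, whether the counting used strand, how long non-coding RNAs were assembled and how circular RNAs and microRNAs were called is not given in the sources used here. For mRNA the authors deposited expected counts per Ensembl transcript for 119414 transcripts, of which 77618 had at least 1 value that was not whole, together with FPKM. Per the file headers the same pair of units, expected count and FPKM, was deposited for 23698 assembled long non-coding transcripts, 5925 of them with no reference gene named. Checked against the values, the deposited FPKM of each of the 2 tables was scaled to the total of its own table. The authors deposited microRNA values as whole-number read counts for 1821 microRNAs (690 known and 1131 predicted). A count of 0 stood beside high counts in other libraries of the same group for several microRNAs, so a 0 there can mean that the microRNA was not listed for that library. For 10673 circular RNAs the deposited values were a score, back-splice junction reads multiplied by a factor of 5.25 to 6.34 per library and truncated to whole numbers. No column of per-sample values was left out.

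Expected counts were summed over the transcripts of a gene, which gave 36096 genes, and rounded to whole numbers. The 1774 transcripts with no gene ID, with 0.533% to 0.601% of a library's counts, stayed out of the tests and of the totals used for scaling. The mRNA totals given here and in the Results include them. Gene symbols and GRCm38 coordinates were taken from the deposited tables. Totals per mRNA library ran from 27074837 to 32100277 counts in controls and from 22144970 to 26842726 in Dnmt3l, and long non-coding totals from 1467252 to 1839502. Small RNA totals ran from 17784876 to 19608955 in controls and from 11397289 to 12378452 in Dnmt3l, and circular RNA junction reads from 16642 to 36573. The fits were tested on simulated data with known changes. For the effect averaged over sexes, mRNA genes changed by 1.5, 2 and 4 times were recovered in 67.2%, 79.1% and 92.4% of cases among 15786 genes, and 4 of 163 calls were false. The same fold sizes were recovered in 0%, 7.46% and 24.2% of cases among 12752 long non-coding transcripts, in 25.4%, 34.3% and 59.1% among 679 microRNAs and in 0%, 2.99% and 37.9% among 1989 circular RNAs. Intervals and floors (3 counts over a group) cover counting error only.

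Genes were tested if at least 3 of the 12 libraries had 0.5 FPKM or more, long non-coding transcripts at 0.1 FPKM, microRNAs at 1 count, and circular RNAs if they were above 0 in at least 6 libraries. Counts were tested with edgeR 4.0.16 (TMM scaling, quasi-likelihood fit and test), and circular RNA scores with limma 3.58.1 (trend) on log2(score + 5), in R 4.3.3. The design fixed before the data were examined named limma for normalized values and edgeR where raw read counts were deposited. The microRNA values were whole-number read counts, and edgeR was therefore used for them. For mRNA and long non-coding RNA the deposited expected counts are estimates and not raw read counts. Testing them with edgeR, rounded, was a judgement that the design did not settle. Each fit held all 12 libraries as 4 group means with 8 residual degrees of freedom. The contrasts were the Dnmt3l effect averaged over sexes, in males, in females, the male effect minus the female effect, and control female minus control male. Values were called at a Benjamini-Hochberg adjusted p below 0.05 within each contrast and kind of RNA, and tests were two-sided. Group levels are library-scaled counts (CPM, with TMM), as mean ± SD over 3 libraries, and errors of log2 changes are standard errors (SE).

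The gene lists were also fixed in advance: 30 gene lists of pathways and cell type markers and 7 microRNA lists. They were tested with camera (limma, preset correlation 0.01), with camera at an estimated correlation and with fry beside it, and 1222 GO terms of 15 to 300 tested genes taken from the deposited mRNA table were tested the same way. Fry tests whether the genes of a list move on balance one way and does not set them against other genes. A list of 35 liver genes and the genes with the widest gap between genotypes were added after the data had been seen. In the test on simulated data camera found 4 of 4 changed lists and called 0 of 40 unchanged ones. Simulated genes were drawn independently, so lists or calls of genes that move together are not covered. In the real data the estimated correlation was 0.118 for GTP binding and 0.418 for GDP binding, for example.

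Named genes followed a fixed rule. For mRNA averaged over sexes these were Dnmt3l and the 10 largest rises and 10 largest falls among called genes with a group mean of at least 1 FPKM and all 6 Dnmt3l libraries on the same side of the controls of their sex, leaving out predicted-gene, Rik and pseudogene symbols. Within a sex 5 and 5 were taken, for the difference between sexes 3 and 3, for long non-coding RNA and microRNA 5 and 5 and for circular RNA 3 and 3. Where fewer than 5 passed in a direction, features of smallest p filled the places and are given as values. Each list contributed up to 4 called members of smallest p, or 2 as values, and GO terms 5 in each direction. Genes ranked by the widest gap are those in which the lowest Dnmt3l library stood farthest above the highest control library or the reverse.

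Alternatives were other pseudocounts, no filter and a stricter filter, median-of-ratios and quantile scaling, the replicate number as a block, library weights, each library left out, only the 6 libraries of a sex, DESeq2 1.42.0 and the estimated correlation. The fit that the design named for normalized values, limma on log2(FPKM + 0.1), was added to the alternatives after the data had been seen. Chosen after that point were also limma on log2(scaled count + 1), edgeR's own low-count filter, microRNAs above 0 in all 12 libraries, and all fits without the 3 control libraries that held liver transcripts. The small RNA columns bear the names of the longer-RNA libraries, numbers included, so each was assigned to a group and not to a sample. Their libraries are lettered a to c within a group in the order of those numbers, and the block was not run for them. Groups were also compared with other splits of the same libraries. No pair of libraries of a group looked like a repeat deposit: the lowest chi-square per degree of freedom between replicates was 7.90 for mRNA and 138 for microRNA. Tables were handled with Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.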

Results

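The medial frontal cortex of mice at postnatal day 28 was profiled in 4 groups of 3 samples, control males, control females, Dnmt3l males and Dnmt3l females, with a ribosomal RNA-depleted library and a small RNA library per sample. Controls carried Emx1-cre, and the Dnmt3l genotype came from crossing those mice with a conditional Dnmt3l knock-in line. The longer-RNA libraries are written CM, CF, DM and DF with the replicate number (DF1 is Dnmt3l female replicate 1), and the small RNA libraries with a letter (DFa), since their columns were assigned to groups and not to samples. The letters follow the column numbers, so the column of DFa bears the name of DF1. Total mRNA counts per library were 27074837 to 32100277 in controls and 22144970 to 26842726 in Dnmt3l. The question was which mRNAs, long non-coding RNAs, microRNAs and circular RNAs differed between genotypes, in both sexes and in each.

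Dnmt3l, the catalytically inactive partner of the de novo DNA methyltransferases, is normally expressed in germ cells and early embryos (ENSMUSG00000000730, chromosome 10, 78041947 to 78063622, GRCm38). Its RNA was present in all 6 Dnmt3l libraries and nearly absent from the 6 controls. The level was 24.2 ± 3.24 CPM in Dnmt3l males and 31.8 ± 12.1 CPM in Dnmt3l females (SD, n = 3 each). Controls held counts of 1, 1 and 0 in males and of 0, 0 and 3 in females. The highest level was in DF1, at 45.8 CPM (1179 counts). The ratio of Dnmt3l to control was 1115 in males (95% counting interval 308 to 9218) and 941 in females (322 to 4565). Within each sex the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 libraries allow. In edgeR the log2 change averaged over sexes was 9.76 ± 0.36 (SE), adjusted p = 6.5e-09, and the male and female changes, 9.85 and 9.67, did not differ (difference 0.18, edgeR adjusted p = 0.971).

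**Figure D1:**
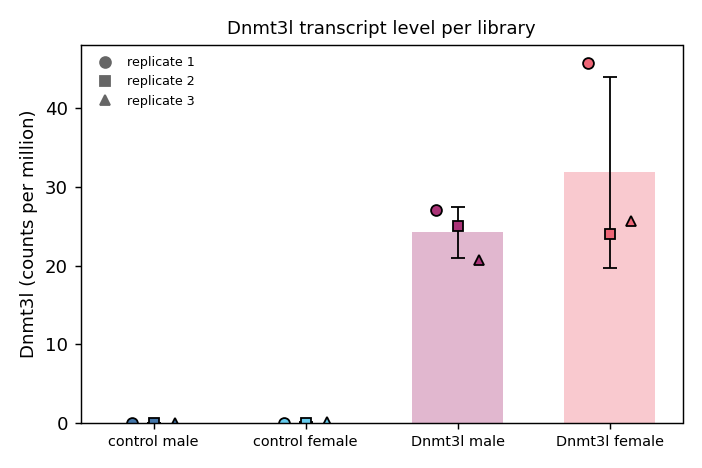
Dnmt3l RNA level in CPM (vertical axis) in the 4 groups (horizontal axis); bars are group means, error bars SD and points the 3 libraries of a group. The Dnmt3l groups average 24.2 and 31.8 CPM, with the highest library, DF1, at 45.8, and both control groups lie near 0.

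Averaged over sexes, the Dnmt3l cortex held more RNA of clustered protocadherins, glutamate receptors and markers of microglia, astrocytes, oligodendrocyte precursors and vessels, and less of immediate early genes, heat-shock genes and markers of excitatory neurons, by camera with its preset correlation. None of these lists was called with an estimated correlation (0 of 30, adjusted p 0.584 to 0.754), and DF1 showed little of the shift. Pcdhga1, a gamma-protocadherin gene (chromosome 18, 37661793 to 37841873), rose from 10.6 ± 1.27 CPM in control males and 9.74 ± 1.17 in control females to 30.4 ± 2.50 and 26.2 ± 5.07 (SD, n = 3 each; log2 change 1.48 ± 0.11 SE, edgeR adjusted p = 1.5e-05). Col7a1, which encodes type VII collagen (chromosome 9, 108953586 to 108984875), rose by 1.73 ± 0.20 on the log2 scale (edgeR adjusted p = 0.000158), from 2.62 ± 0.466 and 2.03 ± 0.528 to 8.56 ± 1.33 and 6.80 ± 2.27 CPM. Dkkl1, a secreted protein of the Dickkopf family known from spermatids (chromosome 7, 45207519 to 45212147), fell from 12.3 ± 2.47 and 14.1 ± 0.950 CPM to 2.80 ± 0.293 and 2.50 ± 0.772 (log2 change −2.31 ± 0.15, edgeR adjusted p = 5.27e-06). Of 15786 genes tested, 3976 rose and 4160 fell (48.9% higher, median absolute log2 change 0.47), and 237 and 228 of them by 2 times or more. Without the 3 control libraries that held liver transcripts (CM3, CF1 and CF2, described with the largest falls) 4359 genes were called, 1920 higher and 2439 lower. With limma on log2 FPKM the split was 2345 higher and 4269 lower (35.5% higher), and with library weights 3237 and 4974 (39.4% higher). The fit with library weights is also limma on log2 FPKM, so these 2 splits are not independent. The median log2 change of all tested genes was 0.0160 with TMM and −0.0579 on deposited FPKM, so the 2 scalings place 0 differently.

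The other largest rises were of modest level. Angpt2, a ligand of the endothelial Tie2 receptor, rose by 1.73 ± 0.28 on the log2 scale (edgeR adjusted p = 0.000517), from 1.03 ± 0.335 CPM in control males to 4.84 ± 1.08 in Dnmt3l males (SD, n = 3). Notch4, a Notch receptor of endothelium, rose by 1.33 ± 0.17 (edgeR adjusted p = 0.000264), from 8.12 ± 1.37 CPM in control females to 18.0 ± 7.39 in Dnmt3l females. Gp1bb, a platelet glycoprotein subunit, rose by 1.51, Tekt2, a structural protein of cilia and flagella, by 1.52, and the transcription factor gene Glis1 by 1.49 (edgeR adjusted p 0.000519, 0.000999 and 0.00107). Trpv6, a calcium channel, rose by 1.39, Rasgrp4, a Ras guanine nucleotide exchange factor, by 1.33, and the pancreatic lipase gene Pnlip by 1.53 (edgeR adjusted p 0.00136, 0.00089 and 0.00815). All 3 were near 1 CPM or below in control males (0.698, 0.984 and 0.383 CPM).

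The 10 largest falls were transcripts of liver proteins and rested on CM3, CF1 and CF2. They were Serpina3k, a serine protease inhibitor, the major urinary protein genes Mup1, Mup3, Mup7, Mup11, Mup19, Mup20 and Mup22, Ahsg (fetuin-A) and Gc (vitamin D-binding protein). Over the groups Serpina3k had 806 counts in controls and 0 in Dnmt3l, at least 214-fold lower against a floor of 3 counts per group, and Mup19, Mup11 and Mup1 were at least 90.1-fold, 74.9-fold and 44.4-fold lower. Mup3, Ahsg, Mup20 and Gc had 1 or 2 counts in Dnmt3l, with control-to-Dnmt3l ratios of 395 (95% counting interval 70.6 to 15649), 341 (60.9 to 13508), 230 (40.9 to 9099) and 124 (33.9 to 1025). Mup7 and Mup22 fell by 7.29 ± 1.81 and 6.95 ± 1.71 on the fitted log2 scale (edgeR adjusted p 0.00492 and 0.00477). The sum of 35 liver genes was 104, 129 and 140 CPM in CM3, CF1 and CF2, 2.32 to 2.77 in the other 3 controls and at most 3.54 in Dnmt3l. All 10 calls ended when CM3 was left out, with edgeR adjusted p from 0.196 (Mup1) and 0.233 (Mup20) to 1.00, and none held without all 3 of those libraries. The Mup genes are near-identical copies whose reads the counting could split, so their separate values are uncertain.

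**Figure D2:**
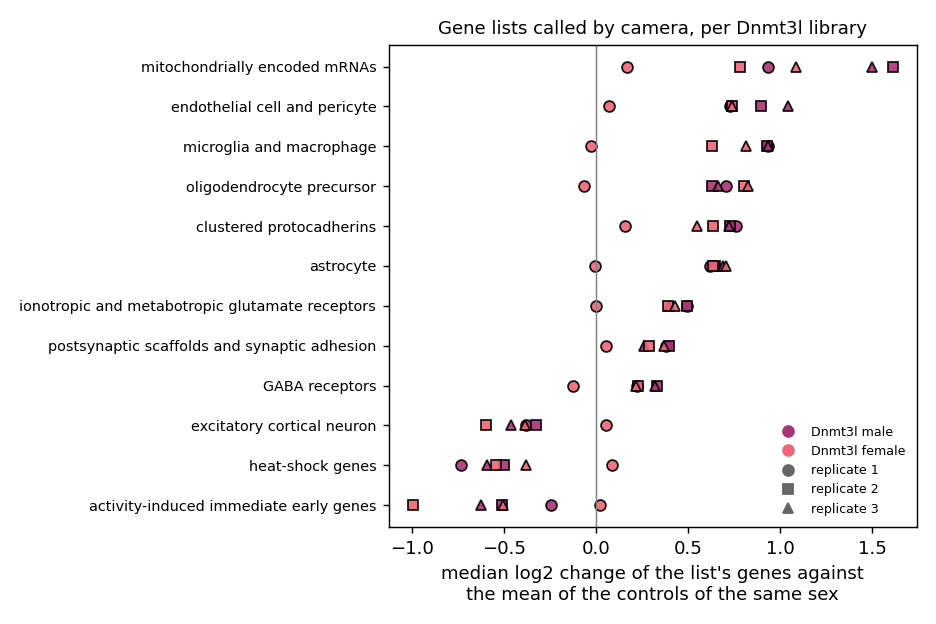
Median log2 change (horizontal axis) of each of the 12 called gene lists (vertical axis) in each Dnmt3l library against the mean of the controls of the same sex; each point is a library, coloured by sex and shaped by replicate. In DF1 the median is 0.158 for clustered protocadherins and −0.0289 for microglia, where the other 5 libraries lie at 0.548 to 0.757 and 0.632 to 0.936.

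Clustered protocadherins, cell adhesion molecules whose alternative promoters give single neurons distinct surface identities, rose in 51 of 57 measured genes and fell in 0 (53 higher and 0 lower adjusted over the list alone). Their median log2 change was 0.61 (camera adjusted p = 1.74e-20, and adjusted p = 0.584 with an estimated correlation). Pcdhb12 rose by 0.90 ± 0.10 and Pcdha11 by 0.66 ± 0.07 (SE, edgeR adjusted p = 0.000142 for both), and their reads may be shared with neighbouring copies. In DF1 the median of the list was 0.158, against 0.548 to 0.757 in the other 5 Dnmt3l libraries. Ionotropic and metabotropic glutamate receptors rose in 24 of 27 genes (24 adjusted over the list alone), with a median of 0.38 (camera adjusted p = 1.21e-07, and adjusted p = 0.584 with an estimated correlation). Grin1, the obligatory NMDA receptor subunit, rose by 0.53 ± 0.08 and Grin2c, another NMDA receptor subunit, by 0.86 ± 0.11 (edgeR adjusted p 0.000318 and 0.000264). Postsynaptic scaffold and synaptic adhesion genes rose in 28 of 40 and fell in 3 (the same counts adjusted over the list alone), with a median of 0.28 (camera adjusted p = 3.61e-06, and adjusted p = 0.584 with an estimated correlation). The scaffolds Shank1 and Shank2 rose by 0.66 ± 0.08 and 0.63 ± 0.08, while Camk2b, a subunit of calcium/calmodulin-dependent kinase, fell by 0.43 (edgeR adjusted p 0.000177, 0.000183 and 0.000264). GABA receptors rose in 7 of 16 genes (7 adjusted over the list alone), with a median of 0.22 (camera adjusted p = 0.0406, and adjusted p = 0.640 with an estimated correlation). The GABA-B subunits Gabbr2 and Gabbr1 rose by 0.57 ± 0.06 and 0.36 ± 0.06 (edgeR adjusted p 0.000152 and 0.000701). The GABA receptor call ended without CM3, CF1, DM2 or DM3 (camera adjusted p 0.0504 to 0.0681).

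Markers of 4 kinds of non-neuronal cell were higher. Of 20 markers of microglia and macrophages 17 rose (18 adjusted over the list alone), and of 20 of endothelial cells and pericytes 18 (19 adjusted over the list alone). Of 17 markers of astrocytes 14 rose, with 1 lower (14 and 1 adjusted over the list alone), and of 11 of oligodendrocyte precursors 9 (9 adjusted over the list alone). Their medians were 0.72, 0.73, 0.58 and 0.70 (camera adjusted p 9.05e-09, 1.34e-10, 1.18e-05 and 0.000901). With an estimated correlation the adjusted p were 0.584, 0.584, 0.584 and 0.640. Examples were Csf1r, the microglial growth factor receptor (0.85 ± 0.12 SE), and Cldn5, a tight junction protein of brain endothelium (1.07 ± 0.13; edgeR adjusted p 0.000306 and 0.000177). Further ones were Slc1a2, the main astrocytic glutamate transporter (0.77 ± 0.10), and Pdgfra, the precursor growth factor receptor (0.96 ± 0.15), with edgeR adjusted p 0.000264 and 0.000425. In DF1 the medians of these 4 lists lay between −0.0668 and 0.0729. Mitochondrially encoded mRNAs rose in 9 of 13 genes (9 adjusted over the list alone), with a median of 1.09 (camera adjusted p = 4.86e-06, and adjusted p = 0.584 with an estimated correlation). The median was 0.37 under quantile scaling, the lowest of the 5 scalings tried. mt-Nd1 and mt-Co1, subunits of respiratory complexes I and IV, rose by 1.18 ± 0.16 and 0.91 ± 0.12 (edgeR adjusted p 0.000291 and 0.000254). Mitochondrial transcripts took 2.63% to 3.59% of counts in controls, 3.73% in DF1 and 5.57% to 7.30% in the other 5 Dnmt3l libraries.

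Immediate early genes induced by neuronal activity fell in 18 of 34 and rose in 2 (19 and 2 adjusted over the list alone), with a median of −0.41 (camera adjusted p = 0.00313, and adjusted p = 0.754 with an estimated correlation). Junb, an AP-1 transcription factor, fell by 1.25 and Nr4a3, a nuclear receptor, by 0.86, while Nptx2, a secreted organizer of synapses, rose by 0.85 ± 0.10 (edgeR adjusted p 0.00203, 0.000264 and 0.000183). Heat-shock genes fell in 12 of 16 and rose in 2 (the same counts adjusted over the list alone), with a median of −0.41 (camera adjusted p = 0.00421, and adjusted p = 0.640 with an estimated correlation). The chaperone genes Hspa8 and Hspd1 fell by 0.55 and 0.50 (edgeR adjusted p 0.000552 and 0.000667). Markers of excitatory cortical neurons fell in 12 of 23 and rose in 4 (14 and 4 adjusted over the list alone), with a median of −0.38 (camera adjusted p = 0.0406, and adjusted p = 0.754 with an estimated correlation). Neurod6, a transcription factor of pyramidal neurons, fell by 1.57, from 73.5 ± 10.1 and 91.0 ± 1.77 CPM in control males and females to 15.8 ± 5.32 and 48.0 ± 24.9 (SD, n = 3, edgeR adjusted p = 0.000273). Bcl11b, a factor of subcortically projecting neurons, fell by 0.67, while the kinase gene Camk2a rose by 0.47 ± 0.07 (edgeR adjusted p 0.000336 and 0.000308). The call of the excitatory list ended without CM1, CM3 or DF2 (camera adjusted p 0.0506 to 0.0936). In DF1 the immediate early and heat-shock medians were 0.0213 and 0.0851, against −0.993 to −0.242 and −0.730 to −0.380 in the other 5 Dnmt3l libraries.

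Camera did not call the other 18 lists. Fry, which sets a list against no other genes, called 13 lists, the 12 that camera called and the neighbours of Dnmt3l. Among 38 genes of the DNA methylation machinery and its readers, Dnmt3l included, 6 rose and 13 fell. The median of that list was −0.06, its mean 0.17 and its test upward (camera adjusted p = 0.993). Mbd6, a methyl-CpG-binding domain protein, rose by 0.77 ± 0.11, and Gadd45g and the corepressor gene Trim28 fell by 0.56 and 0.32 (edgeR adjusted p 0.000293, 0.00135 and 0.00205). Of 47 imprinted genes 10 rose and 16 fell (median −0.09, camera adjusted p = 0.471), with Atp10a 1.02 ± 0.11 higher and Ndn, of the Prader-Willi region, at −0.76 ± 0.09 (edgeR adjusted p 0.000158 and 0.000177). Of 12 germline genes usually silenced by promoter methylation, Sycp2 rose by 0.65 and Tdrkh and Brdt fell by 0.28 and 0.36 (edgeR adjusted p 0.0249, 0.0132 and 0.0268), while 9 did not pass. That list had a median of 0.05, a mean of 0.00 and a downward test (camera adjusted p = 0.993). Sycp2 was not called without CM2, CM3, CF1, DM3 or DF1 (edgeR adjusted p 0.0520 to 0.0890), nor Brdt without CM1, CF3, DM1, DM3, DF2 or DF3 (0.0511 to 0.0601). Of 10 genes that neighbour Dnmt3l, 2 rose and 5 fell (median −0.19, camera adjusted p = 0.326, fry adjusted p = 0.00163 in limma). The medians of the neighbours were below 0 in all 6 Dnmt3l libraries (−0.373 to −0.0648, the latter in DF1), with Gatd3a, Rrp1 and Pfkl at −0.69, −0.56 and −0.47 (edgeR adjusted p 0.000399, 0.00133 and 0.000624).

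Interneuron markers rose in 7 of 23 and fell in 10 (median 0.17, mean −0.06, downward test, camera adjusted p = 0.993). Gad1 and Gad2, the enzymes of GABA synthesis, and the calcium-binding protein gene Calb2 fell, with log2 changes of −0.69 ± 0.10, −0.73 ± 0.10 and −1.24 ± 0.15 (edgeR adjusted p 0.000383, 0.000293 and 0.000206). Mature oligodendrocyte markers rose in 7 of 25 and fell in 3 (0.18, camera adjusted p = 0.353). Presynaptic release genes rose in 12 and fell in 11 of 34 (median 0.07, mean −0.06, upward test, 0.896), and autism and neurodevelopmental risk genes in 15 and 12 of 45 (median 0.06, mean −0.01, upward test, 0.941). Monoamine receptors rose in 4 of 23 (2 adjusted over the list alone; median 0.16, camera adjusted p = 0.326), all of them noradrenaline receptors. Interferon-stimulated genes rose in 5 of 26 and fell in 2 (0 and 0 adjusted over the list alone; 0.06, 0.712), glucocorticoid-induced genes in 5 and 4 of 17 (median −0.02, mean 0.07, downward test, 0.941) and sex markers in 3 and 2 of 8 (0.17, 0.993). Markers of other tissue were called in 8 and 1 of 15 for meningeal fibroblasts (0.30, 0.0741), 1 and 1 of 15 for choroid plexus (median 0.09, mean −0.05, downward test, 0.941), and 0 and 4 of 17 for striatum (−0.35, 0.0888), each as higher and lower, median log2 change and camera adjusted p. In the same order the values were 3 and 2 of 12 for olfactory bulb and septum (0.16, 0.871), 2 and 4 of 12 for thalamus and hippocampus (−0.24, 0.326) and 0 and 4 of 5 for red blood cells (−0.99, 0.0741). Adjusted over the list alone the counts were 13 and 11 for presynaptic genes, 16 and 12 for risk genes, and 3 and 5 for the neighbours of Dnmt3l. They were 1 and 0 for choroid plexus, 0 and 3 for striatum and 0 and 5 for red blood cells, and those of the other uncalled lists stayed as given. The medians of the DNA methylation, germline, glucocorticoid and choroid plexus lists changed sign with the scaling.

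**Figure D3:**
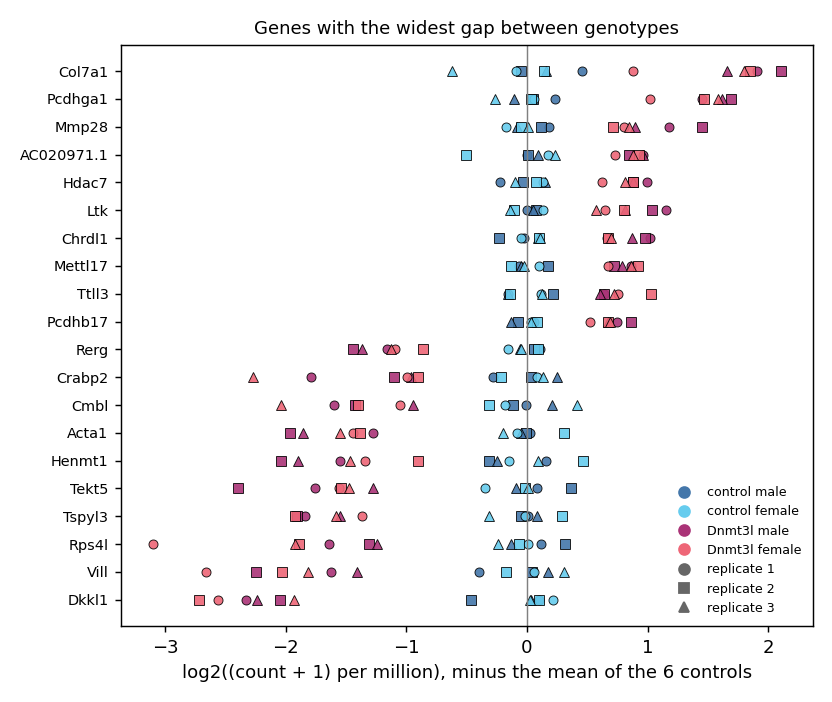
Log2 CPM of (count + 1), minus the mean of the 6 controls (horizontal axis) for the 20 genes with the widest gap between genotypes (vertical axis); each point is a library, coloured by group and shaped by replicate. Every Dnmt3l library, DF1 included, lies beyond all 6 controls for each gene, with Dkkl1 (−2.31) the largest fall and Col7a1 (1.73) the largest rise on the fitted log2 scale.

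A set of genes separated the genotypes fully. All 6 Dnmt3l libraries lay above all 6 controls for 863 genes (5.47%) and below them for 1078 (6.83%), where chance gives 17.1 genes each (0.108%). The genes with the widest gap, a ranking chosen after the values were seen, included Pcdhga1, Col7a1 and Dkkl1. Others were Hdac7, a class II histone deacetylase (0.84 ± 0.08 SE, to 48.3 ± 2.26 CPM in Dnmt3l males and 43.7 ± 4.02 in Dnmt3l females, SD, n = 3), and Chrdl1, an X-linked antagonist of bone morphogenetic proteins (0.81 ± 0.08; edgeR adjusted p = 0.000115 for both). Mmp28, Mettl17, Ltk, Ttll3, Pcdhb17 and the protocadherin-region gene AC020971.1 rose by 0.70 to 0.99. Tspyl3, a retrogene of the nucleosome assembly protein family, fell by 1.70, from 23.0 ± 1.08 and 22.9 ± 4.81 CPM to 6.71 ± 0.930 and 7.45 ± 1.43 (edgeR adjusted p = 1.5e-05). Vill, Rps4l, Acta1, Tekt5, Henmt1, Cmbl, Crabp2 and Rerg had log2 changes of −1.97 to −1.18 (edgeR adjusted p 7.55e-05 to 0.00173), among them skeletal muscle actin (Acta1), a retinoic acid-binding protein (Crabp2) and the piRNA methyltransferase Henmt1. Rps4l shares sequence with its parent ribosomal gene, and its count is uncertain.

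Among GO terms, genes of homophilic cell adhesion rose in 63 of 92 (median log2 change 0.47), of G-protein coupled receptor activity in 114 of 201 (0.44) and of olfactory receptor activity in 56 of 91 (0.45), with camera adjusted p 7.15e-15, 1.09e-10 and 4.19e-09. Smell perception had 46 of 70 higher (0.45) and G-protein coupled receptor signalling 138 of 268 (0.42), with camera adjusted p = 8.36e-09 for both. Genes of GDP binding fell in 30 of 38 (−0.55), and of small GTPase signal transduction in 79 of 139 (−0.41), with camera adjusted p 3.62e-08 and 2.07e-07. GTP binding had 154 of 300 lower (−0.26), GTPase activity 97 of 176 (−0.31) and threonine-type endopeptidase activity, which proteasome subunits carry, 14 of 22 (−0.50), with camera adjusted p 1.64e-05, 2.46e-05 and 0.000774. In DF1 the medians of these 10 terms were −0.0878 to 0.149. Camera called 123 terms higher and 53 lower of 1222 (364 at an unadjusted p below 0.05), and 0 with an estimated correlation (adjusted p = 0.633 for each of the 10).

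**Figure D4:**
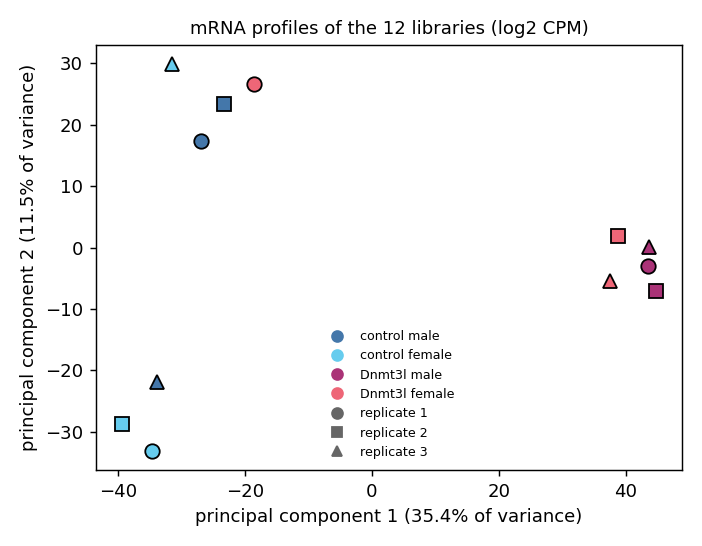
The first principal component of the mRNA libraries (35.4% of variance, horizontal axis) against the second (11.5%, vertical axis); each point is a library, coloured by group and shaped by replicate. DF1 lies at −18.5 on the first component, between the controls (−39.3 to −23.3) and the other 5 Dnmt3l libraries (37.5 to 44.7).

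Among the genes that rose most in males, Angpt2 rose by 2.22 ± 0.40 on the log2 scale (SE, edgeR adjusted p = 0.00179). Pglyrp1, a peptidoglycan recognition protein of innate immunity, rose from 5.41 ± 1.08 to 20.6 ± 1.24 CPM (SD, n = 3; 1.93 ± 0.39, edgeR adjusted p = 0.00255). Acr, the sperm protease acrosin, rose by 1.83 and Depp1, a FoxO-regulated gene of autophagy, by 1.89 (edgeR adjusted p 0.00470 and 0.0150). The largest falls were of Hcrt, the hypothalamic neuropeptide orexin, with 63 counts in control males and 0 in Dnmt3l males (at least 16.3-fold lower, edgeR adjusted p = 0.0279), and of liver transcripts. Mup7, Mup22, Cyp2e1 and Adh1 had 1 to 3 counts in Dnmt3l males. Their ratios of control to Dnmt3l were 172 (95% counting interval 47.4 to 1425), 114 (38.9 to 557), 87.8 (15.4 to 3498) and 61.4 (10.7 to 2454). In edgeR 3225 genes rose and 3577 fell of 15786 (47.4% higher). The split was 1630 and 3733 with limma on log2 FPKM (30.4% higher) and 2531 and 4758 with library weights (34.7%), and 3684 genes were called without CM3, CF1 and CF2. Calls ended for Depp1 without CM2 or DM2 (edgeR adjusted p 0.0570 and 0.0626) and for Hcrt without CM2 or any Dnmt3l male (0.0643 to 0.190). The same held for Cyp2e1 without CM3 or any Dnmt3l male (edgeR adjusted p 0.0890 to 0.420) and for Adh1 without CM3 (0.0624). For Mup7 and Mup22 calls ended without CM3, where the changes became 2.76 and 1.08, and without CF1, CF2, DM1, DM2, DM3, DF2 or DF3.

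Of the gene lists in males camera called 9 higher and 2 lower, and 0 with an estimated correlation. Fry also called 11, without the immediate early genes and with the neighbours of Dnmt3l (median −0.25, fry adjusted p = 0.00558 in limma). Clustered protocadherins rose in 52 of 57 genes (55 adjusted over the list alone; median 0.69), glutamate receptors in 20 of 27 (21; 0.47), GABA receptors in 8 of 16 (8; 0.31) and postsynaptic genes in 26 of 40 with 3 lower (27 and 3; 0.35), with camera adjusted p 3.19e-21, 6.70e-08, 0.00892 and 1.99e-06. Microglial markers rose in 16 of 20 (17; 0.93), endothelial in 17 of 20 (19; 0.92), astrocytic in 13 of 17 (13; 0.69), precursor markers in 6 of 11 (8; 0.65) and mitochondrial mRNAs in 9 of 13 (9; 1.35), with camera adjusted p 3.89e-09, 1.31e-10, 9.82e-07, 0.00295 and 9.82e-07. Heat-shock genes fell in 9 of 16 (9 with 1 higher; −0.57) and immediate early genes in 12 of 34 with 2 higher (12 and 2; −0.42; camera adjusted p 0.000399 and 0.00941). With an estimated correlation the adjusted p of these 11 lists were 0.490 to 0.763. Excitatory neuron markers were not called (camera adjusted p = 0.0718).

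In females Tekt2, Col7a1 and Glis1 had the largest rises and liver transcripts and Dkkl1 the largest falls. Tekt2 rose by 1.82 ± 0.42 (SE), Col7a1 by 1.74 ± 0.28, Glis1 by 1.62, Icam2, an endothelial adhesion molecule, by 1.52 and Gp1bb by 1.48 (edgeR adjusted p 0.0331, 0.0194, 0.0362, 0.0401 and 0.0361). Dkkl1 fell by 2.50 and Vill, a villin-like actin-binding protein, by 2.24 (edgeR adjusted p 0.000167 and 0.00457), and both were called without any single library. The liver transcripts Alb (albumin), Cyp2e1 and Apoh fell as well (edgeR adjusted p 0.0494, 0.0462 and 0.0464), and among the control females CF1 and CF2 held them. In edgeR 746 genes rose and 691 fell of 15786 (51.9% higher). That count moved with every library left out, to 7443 without DF1, 454 without DM3 and 141, 142 and 100 without CM1, CM2 and CM3. It was 53, 7 and 18 without CF1, CF2 and CF3, 114 and 87 without DM1 and DM2, and 13 and 43 without DF2 and DF3. With limma on log2 FPKM 93 were higher and 282 lower (24.8% higher), with library weights 1649 and 2948 (35.9%), with DESeq2 3221 were called, and 2 each with only the 6 female libraries and without CM3, CF1 and CF2. Glis1, Icam2, Gp1bb, Cyp2e1 and Apoh lost their calls without any library but DF1 (edgeR adjusted p 0.0503 to 0.163), and Tekt2 without any but DM3 and DF1 (0.0506 to 0.129). Alb lost its call without any but CM3 and DF1 (edgeR adjusted p 0.0560 to 0.167), and Col7a1 without CF1, CF2, CF3, DF2 or DF3 (0.0506 to 0.0997).

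DF1 stood apart from the other Dnmt3l females. Of the 6802 genes called in males it moved in the same direction as males for 62.4% (slope 0.180), against 95.1% (0.707) in DF2 and 97.4% (0.720) in DF3. Of the gene lists in females camera called 8 higher and 3 lower. With an estimated correlation it called none (adjusted p 0.693 to 0.734 for these 11), and fry called 1 list, the neighbours of Dnmt3l (fry adjusted p = 0.0483 in limma), and none of the 11. Protocadherins rose in 24 of 57 genes (42 with 1 lower adjusted over the list alone; median 0.49), glutamate receptors in 5 of 27 (9; 0.28) and postsynaptic genes in 10 of 40 with 2 lower (18 and 2; 0.23), with camera adjusted p 1.12e-15, 5.90e-06 and 6.00e-05. Microglial markers rose in 7 of 20 (13; 0.55) and endothelial markers in 9 of 20 (15; 0.56), with camera adjusted p 1.03e-06 and 1.26e-08. Astrocytic markers rose in 4 of 17 with 1 lower (7 and 1; 0.46), precursor markers in 2 of 11 (7; 0.56) and mitochondrial mRNAs in 5 of 13 (7; 0.68), with camera adjusted p 0.00151, 0.000558 and 0.000371. Striatal markers fell in 2 of 17 (2; −0.73), immediate early genes in 2 of 34 with 1 higher (2 and 1; −0.38) and excitatory markers in 2 of 23 with 1 higher (3 and 1; −0.33; camera adjusted p 0.000128, 0.00150 and 0.0301). The striatal median was −1.45 in DF1, −1.56 in DF2 and 0.336 in DF3.

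The genotype effects in males and females overlapped. They share no library, but both came from the fit of all 12 libraries, with a common estimate of each gene's spread. Of the genes called in males 96.5% of those higher and 96.9% of those lower had the same sign in females. In both sexes 634 were called higher and 630 lower, where independent lists would share 152 and 157. Those figures are no strict baseline, since the common estimate favours genes of small spread in both lists. The shared counts moved with every library left out, to 2629 and 3517 without DF1, 218 and 174 without DM3, 69 and 56 without CM1, 67 and 58 without CM2, and 46 and 43 without CM3. They were 25 and 25 without CF1, 2 and 5 without CF2, 6 and 12 without CF3, 56 and 47 without DM1, 41 and 36 without DM2, 5 and 7 without DF2, and 13 and 16 without DF3. DESeq2 gave 1306 and 1478, library weights 1176 and 2732, quantile scaling 63 and 77, and the fit without CM3, CF1 and CF2 2 and 0. limma on log2 FPKM gave 68 and 262 with 1 added, 68 and 228 with 0.1 and 56 and 184 with 0.01. More were thus shared lower than higher there and with library weights, which is also a limma fit on log2 FPKM. The test of the difference between sexes called 0 genes with edgeR (1120 at an unadjusted p below 0.05, 5 called by DESeq2, 26 by edgeR without DF1). Its smallest p belonged to genes that did not pass. Kif5a, a neuronal kinesin, Cntn4, an adhesion molecule, and Fam107a had differences (male minus female effect) of 0.56, 0.54 and 0.65. The phosphatase gene Ptpn2, Ndor1 and Napepld, the enzyme that forms N-acylethanolamines, had differences of −0.65, −1.90 and −0.76 (edgeR adjusted p = 0.679 for all 6). In the difference 12 lists were higher and 3 lower, led by protocadherins (median difference 0.28, camera adjusted p = 1.80e-10) and choroid plexus (−1.32, camera adjusted p = 8.38e-08). The choroid plexus median was −1.06 in DF1, within the males' −1.30 to −0.267, and 1.182 and 1.505 in DF2 and DF3. With an estimated correlation the adjusted p was 0.391 for both, and 0.391 to 0.847 over the 15 lists.

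The genes called between control females and control males were all Y-linked. Uty, Ddx3y, Eif2s3y and Kdm5d, each with an X-linked partner, had log2 changes (female minus male) of −7.36, −8.01, −8.82 and −1.50 (edgeR adjusted p 0.000178, 0.000197, 0.00140 and 0.000109). Kdm5d kept 27.5 ± 1.30 CPM in control females (SD, n = 3), where reads may be shared with its X-linked partner Kdm5c. Values for the X-linked Eif2s3x, Kdm6a, Ddx3x and Kdm5c were 0.64, 0.56, 0.39 and 0.27 and did not pass (edgeR adjusted p = 1 for each). In DF3 the Y-linked Uty, Ddx3y and Eif2s3y stood at 3.04, 1.97 and 3.59 CPM, against at most 0.333 in the other 5 female libraries. Of 15786 genes 4 were called, 5 without CM1 or without DF1, and 0 without CM3, CF1 and CF2.

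Fewer long non-coding transcripts were called, which does not show that fewer changed. They were tested per transcript and not summed by gene. In the test on simulated data 7.46% of 2-fold changes were recovered for them, against 79.1% for mRNA. At an unadjusted edgeR p below 0.05 were 1563 of 12752. The transcript Gm9866 on chromosome 12 fell from 241 ± 41.2 CPM in control males and 149 ± 15.1 in control females to 24.5 ± 11.2 and 61.2 ± 21.8 (SD, n = 3; log2 change −2.29 ± 0.25 SE, edgeR adjusted p = 0.00456). Gm16758 on chromosome 17 had 147 counts over the controls and 0 over the Dnmt3l libraries, at least 50.2-fold lower (edgeR adjusted p = 0.0166). A transcript annotated to Blnk, a B-cell adaptor gene (chromosome 19, 40928927 to 40994535), was higher, with a fitted log2 change of 3.82 ± 0.46 (edgeR adjusted p = 0.00578). That value measures no size, since it rests on control males with 3 counts in all (0.618 CPM). In females the Blnk transcript was not called (0.30, edgeR adjusted p = 0.951), with 85.6 CPM in controls and 106 in Dnmt3l. A transcript at Sfxn5, a mitochondrial carrier gene, rose by 1.84 ± 0.27 (edgeR adjusted p = 0.0134). These 4 were called without any single library. Of 12752 transcripts 38 were higher and 25 lower. That count was 177 without DF1, 33, 27 and 30 without CM1, CM2 and CM3, and 28 and 34 without CF2 and CF3. It was 32, 34 and 32 without DM1, DM2 and DM3, 29 and 40 without DF2 and DF3, and 6 without CM3, CF1 and CF2, and DESeq2 called 554. TCONS_00366639 (2.40, edgeR adjusted p = 0.0313), TCONS_00056696 (2.21, 0.0190) and a transcript at Sfi1 (1.80, 0.0451) were also higher and Gm48678 (−4.35, 0.0296), Gm50214 (−3.10, 0.0359) and a transcript at the protocadherin-like gene Dchs1 (−2.48, 0.0190) lower. The first was not called without any library but CF1, CF3 and DF1 (edgeR adjusted p 0.0612 to 0.0937), nor the others without CM2, CF1, CF2 or DM3 (TCONS_00056696, 0.0502 to 0.0683) and CM1, CM3 or any Dnmt3l male (Dchs1, 0.0504 to 0.0709). Sfi1 kept its call only without DF1 or DF3 (otherwise edgeR adjusted p 0.0555 to 0.131), Gm48678 without CF1, DM3 or DF1 (0.0527 to 0.0819) and Gm50214 without CM3, DF1 or DF3 (0.0601 to 0.0982). Whether counting used strand is not given in the sources used here, so reads of a coding gene and an overlapping or antisense transcript cannot be told apart.

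In males 13 long non-coding transcripts rose and 5 fell. Runx2os1, antisense to the osteoblast factor gene Runx2 (chromosome 17, 44735845 to 44737612), had 195 counts over Dnmt3l males and 0 over control males (at least 62.6-fold higher, edgeR adjusted p = 0.00417). The Blnk transcript had 572 and 3 (ratio 184, 95% counting interval 62.5 to 892, edgeR adjusted p = 0.00300). TCONS_00519701 rose by 1.45 and TCONS_00519703 by 1.29 (edgeR adjusted p 0.00348 and 0.00881), and Sfxn5 by 2.47 (0.0381). A transcript at Arhgap15 had 474 counts over control males and 0 over Dnmt3l males (at least 164-fold lower, edgeR adjusted p = 0.00300). Gm9866, Gm26782, 2900072N19Rik and A830082N09Rik fell by 3.29, 1.64, 1.27 and 0.92 (edgeR adjusted p 0.00348, 0.0385, 0.0266 and 0.0403). The count of 18 became 10, 9 and 10 without CM1, CM2 and CM3, 9 without DM3, 59 without DF1, 39 without DF3, 12 without CF2 or DM1 and 7 without CM3, CF1 and CF2, and DESeq2 called 449. TCONS_00519703 was not called without CM2, CM3 or DM3 (edgeR adjusted p 0.0593 to 0.0933). Calls held only without CF1, CF3, DF1 or DF3 for Sfxn5 (otherwise edgeR adjusted p 0.0529 to 0.159), without DF1 or DF3 for Gm26782 (0.0547 to 0.178), without CF1, CF3 or any Dnmt3l female for 2900072N19Rik (0.0514 to 0.147) and without CF3, DF1 or DF3 for A830082N09Rik (0.0509 to 0.163). In females edgeR called 0 (812 at an unadjusted p below 0.05, 136 called by DESeq2, 11 by edgeR without DF1, 1 without CF1, CF3 or DF3). Values of small p included 4930527B05Rik 0.56, 5530401A14Rik 0.48 and Gm3764 0.61 among higher and Gm17753 −1.04, Gm26782 −1.56 and 1700001L05Rik −1.06 among lower transcripts (edgeR adjusted p 0.146 for the first and 0.171 for the others). Gm50214 had 46 counts over control females and 1 over Dnmt3l females (ratio 46.3, 95% counting interval 7.91 to 1870). The difference between sexes was called for Runx2os1, Blnk and Arhgap15 (edgeR adjusted p = 0.0401 each). Control males differed from the 9 other libraries at Runx2os1 and Blnk, with 0 to 1.85 CPM against 33.1 to 134, and Dnmt3l males at Arhgap15, with 0 against 12.5 to 120. That count of 3 was 0 without CM1, CM3, CF2, DM1, DM3, DF1 or DF2 and 1 without CM2 or DM2. Calls held only without CF1 or CF3 for Runx2os1, without CM2 or CF3 for Blnk and without CF1, CF3 or DF3 for Arhgap15 (otherwise edgeR adjusted p 0.0624 to 0.133).

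Among microRNAs, miR-466d-3p of the Sfmbt2 intronic cluster fell from 16.9 ± 0.757 CPM in control males and 18.0 ± 0.861 in control females to 1.28 ± 0.281 and 1.81 ± 0.401 (SD, n = 3; log2 change −3.51 ± 0.16 SE, edgeR adjusted p = 6.44e-07). miR-135b-5p rose from 861 ± 16.3 and 889 ± 26.8 CPM to 1026 ± 32.0 and 1104 ± 55.5 (0.28 ± 0.04, edgeR adjusted p = 0.0112, and 0.0502 without CMb). miR-144-5p, processed with the erythroid miR-451, fell by 1.05 and miR-499-5p, hosted by a myosin gene, by 0.98 (edgeR adjusted p 0.00150 and 0.000392). miR-466c-3p, miR-324-5p and miR-134-5p, a dendritic microRNA of the Dlk1-Dio3 cluster, rose by 0.53 ± 0.12, 0.44 ± 0.09 and 0.31 ± 0.07 (edgeR adjusted p 0.0428, 0.0409 and 0.0409). miR-466 copies have near-identical sequences that the counting could split. Of 679 microRNAs 7 were higher and 13 lower. The count was 121 without DFa, 8, 5 and 6 without CMa, CMb and CMc, 7, 7 and 8 without CFa, CFb and CFc, 11, 9 and 9 without DMa, DMb and DMc, and 10 without DFc, and DESeq2 called 73. Calls held only without DMa or DFa for miR-466c-3p (otherwise edgeR adjusted p 0.0549 to 0.125) and without DFa or DFb for miR-324-5p (0.0551 to 0.103) and miR-134-5p (0.0639 to 0.108).

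Several called microRNAs were listed at 0 in whole groups. miR-127-3p of the Dlk1-Dio3 cluster was listed at 0 in DMa and all 3 Dnmt3l females, beside 13446 and 10226 CPM in DMb and DMc and 13028 to 16302 in controls (edgeR adjusted p = 0.0493, and 0.0660 to 0.121 without any library but DMa and DFa). miR-6936-3p, miR-6939-3p, miR-6986-5p and miR-694 were listed at 0 in all 6 Dnmt3l libraries, with 66, 51, 34 and 29 counts over the controls (edgeR adjusted p 0.0229, 0.0409, 0.0493 and 0.0493). Calls ended for miR-6936-3p without any control (edgeR adjusted p 0.0618 to 0.0905), for miR-6939-3p without any library but DFa and DFb (0.0615 to 0.109) and for miR-6986-5p and miR-694 without any but DFa (0.0605 to 0.134). Of the 709 to 731 microRNAs listed per control library and 473 to 640 per Dnmt3l library, 15 were at 0 in some libraries and at 1000 counts or more in others. Of these 15, 9 were at 0 only in Dnmt3l libraries and 0 only in controls. In males miR-466d-3p, miR-144-5p, miR-34b-3p and miR-499-5p fell by 3.71, 1.48, 1.11 and 1.07 (edgeR adjusted p 1.25e-05, 0.00224, 0.0152 and 0.00317). miR-7019-3p was listed at 0 in the 3 Dnmt3l males and at 2.24 to 3.15 CPM in the other 9 libraries (154 counts over control males, edgeR adjusted p = 3.32e-05). Those 5 calls were 54 without DFa and 20 without DFb, and miR-34b-3p was not called without CMb, CMc, DMa or DMc (edgeR adjusted p 0.0724 to 0.0841). In females miR-466d-3p and miR-499-5p fell by 3.31 and 0.90 (edgeR adjusted p 3.07e-05 and 0.0269). miR-499-5p was not called there without any control or DFb (edgeR adjusted p 0.0586 to 0.182), and the count of 2 was 49 without DFa, 4 without DFc and 1 without CMa, CMb, CMc, CFa or DFb. The difference between sexes was called for miR-7019-3p alone (edgeR adjusted p = 0.000189), with 11 microRNAs without DFb, 3 without DMc and 2 without CMa, DMa or DFa.

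By list, 42 microRNAs of the imprinted Dlk1-Dio3 cluster had a median log2 change of 0.13 with an upward test (camera adjusted p = 0.000402, and adjusted p = 0.629 with an estimated correlation), 1 rising (miR-134-5p) and 1 lower (miR-127-3p). Erythroid and vascular microRNAs (6 measured, miR-144-5p lower) had a median of −0.36 (camera adjusted p = 0.0450, and adjusted p = 0.629 with an estimated correlation), beside red blood cell mRNAs, of which 4 of 5 fell (median −0.99, camera adjusted p = 0.0741). Brain-enriched microRNAs had a median of −0.14 (19 measured, camera adjusted p = 0.770) and the miR-29, miR-148 and miR-152 families, which target DNA methyltransferase mRNAs, of −0.20 (7, 0.911). The medians of the Sfmbt2 cluster and the let-7 family were 0.25 (14, camera adjusted p = 0.261) and −0.21 (9, 0.261), and that of activity-regulated microRNAs −0.06 with an upward test (6, 0.770). Adjusted over the list alone the counts of these 7 lists were the same.

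The largest change among circular RNAs was of a pair on the unplaced scaffold JH584304.1. The junction from 25369 to 60857 scored 5805 to 14060 in Dnmt3l males and 767 to 13619 in Dnmt3l females, against 0 to 572 in control males and 329 to 538 in control females (log2 change 4.70 ± 0.45 SE, limma adjusted p = 1.01e-13). The one from 25369 to 59773 scored 55 to 1462 in Dnmt3l and 0 to 40 in controls (5.06 ± 0.53, limma adjusted p = 3.3e-12). A circle of Spred2, an inhibitor of Ras signalling (chromosome 11, 19998120 to 20008477), fell by 1.69 (limma adjusted p = 0.00231), from 307 ± 64.4 in control females to 82.7 ± 70.8 in Dnmt3l females (SD, n = 3). Circles of Pms1 and Fam135a, added after their values were seen, fell by 2.85 and 2.75 (limma adjusted p = 0.0236 each). Values that did not pass were Tshz2 1.27, Strbp −0.94 and Snhg11 −1.04 (limma adjusted p 0.254, 0.0719 and 0.0719). Of 1989 circular RNAs 2 were higher and 3 lower, 33 were called without DF1, and 3 without CF1, CF2, CF3, DM2, DF2 or DF3.

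In males the scaffold pair (6.38 and 6.12, limma adjusted p 6.5e-13 and 2.09e-09) and a circle of Tshz2, a zinc-finger gene (chromosome 2, 169883526 to 169886459), were higher. Tshz2 was listed at 353, 0 and 414 in control males and scored 414, 656 and 524 in Dnmt3l males (limma adjusted p = 0.0286), and was called only without CM1, CM3, CF2 or CF3 (otherwise limma adjusted p 0.0834 to 0.982). The count of 3 was 5 without DM3. In females the scaffold pair rose (by 3.01 for the junction to 60857, limma adjusted p 0.00777 and 0.00133) and Spred2 (−2.10, 0.0231) and a circle of the postsynaptic scaffold gene Dlgap1 (−2.50, 0.0485, chosen after its values were seen) were lower. The count of 4 was 37 without DF1, 1 without CF1 and 2 without CF2, CF3 or DF3, and Spred2 was not called without CF1, CF2, CF3, DF2 or DF3 (limma adjusted p 0.119 to 0.218). The junction to 60857 was not called in females without CF1, DF1 or DF2 (limma adjusted p 0.0919 to 0.730), nor that to 59773 without DF2 (0.190). No difference between sexes was called (0 of 1989 with limma, 98 at an unadjusted p below 0.05, 2 without CM1 and 3 without CM3).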

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

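All tests of explanations in this part were chosen after the results they bear on were seen.

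The gap between an extreme library and its nearest neighbour was tested in 30 groups of 6 libraries. In 10 of them it was flagged, each time for DF1, the Dnmt3l female with the most Dnmt3l RNA. The 30 include groups of controls and of small RNA libraries, to which DF1 does not belong. Chance gives about 1 in 20 groups such a gap, which is 1.5 of all 30 and not of those with DF1. The groups share libraries and are not independent, and the gene lists among them were those called in these same libraries. The first principal component of DF1 was −18.5 (others 37.5 to 44.7), its Dnmt3l level 45.8 CPM and its liver transcripts 1.903 CPM. List medians (log2 change) in DF1 were 0.158 for clustered protocadherins, −0.00198 for glutamate receptors, −0.123 for GABA receptors, −0.0668 for oligodendrocyte precursors, −0.00323 for astrocytes, −0.0289 for microglia and 0.0729 for endothelial cells and pericytes. The small RNA library DFa, whose column bears the name of DF1, was not flagged. It had 640 microRNAs listed, against 473 to 562 in the other Dnmt3l libraries, and without it the 20 microRNA calls averaged over sexes became 121. Whether DF1 and DFa came from the same sample was not settled here.

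The shift of many mRNAs in 5 of 6 Dnmt3l libraries, with a small shift in DF1, could have several explanations. A lower share of all neurons in the tissue is argued against as the whole cause by glutamate receptor genes, of which 24 of 27 rose and 0 fell, while markers of excitatory neurons fell in 12 of 23 with 4 higher (median −0.38), and those of interneurons fell in 10 (Gad1, Gad2 and Calb2 among them) and rose in 7 of 23 (median 0.17), so a loss of some kinds of neuron stays open. The amount of Dnmt3l RNA in the tissue as the measure of the shift stays open: DF1 had the most Dnmt3l RNA and a protocadherin median of 0.158 against at least 0.548 in the other 5, but 1 library excludes nothing. Handling of tissue or RNA that differed between genotypes stays open: every control had a larger small RNA total than every Dnmt3l library, with the lowest control 1.44 times the highest Dnmt3l library, and the labels give no batch, so genotype and handling cannot be told apart. An effect of the knock-in on these genes in 5 animals or samples, with DF1 unlike them for another reason, also stays open and was not tested.

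Liver transcripts in CM3, CF1 and CF2 were in similar proportions across 35 genes in the 3 libraries. The lowest Spearman correlation between a pair was 0.868, as liver RNA carried into these libraries would give, although the route was not tested. Lowering of liver transcripts in cortex by Dnmt3l is argued against by the other 3 controls, of which the highest had 2.77 CPM, within the range of the Dnmt3l libraries. On the second principal component CM3, CF1 and CF2 lay at −33.1 to −21.8 and the other 3 controls at 17.4 to 29.8, beside DF1 at 26.5.

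A set of 128 genes, 67 higher and 61 lower, was displaced by at least 0.5 on the log2 scale in the same direction in all 6 Dnmt3l libraries, DF1 included. It holds the liver gene Apoh, at 1.24 to 2.10 CPM in CM3, CF1 and CF2 and at most 0.173 in the other controls. A chromosome segment around the Dnmt3l gene itself is argued against for the set. Of its genes 2 lay within 20 Mb of Dnmt3l, where random draws gave 3.01 (permutation p = 0.807). The site of the knock-in is not stated here, so that count does not cover a segment around an insertion at another site. The fixed list of 10 genes next to Dnmt3l was lower by fry (limma, adjusted p = 0.00163) with a median below 0 in each Dnmt3l library. That leaves a segment or local effect open for those neighbours. Segments of another strain elsewhere in the genome stay open. With the 4 clustered protocadherins left out 40 of 124 genes (32.3%) had another within 2 Mb. Random draws gave 33.2 genes, fewer than observed but not significantly so (permutation p = 0.160). With Gm37388, Gm36858 and AC020971.1 from the same stretch of chromosome 18 left out too, 37 of 121 genes (30.6%) had another, against 31.8 genes (permutation p = 0.222). Most genes of the set had no such neighbour, but this test cannot exclude a small excess. Single genes of the set near a local variant stay open, and an effect of Dnmt3l on these genes is an untested hypothesis.

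Differences between sexes in the genotype effect were called for a few features, with the animals' sex and the chance of few samples both left open. The tests of the difference gave fitted log2 values of 8.96 for the long non-coding transcript Runx2os1, 7.03 for the Blnk transcript and −10.31 for the Arhgap15 transcript. These values depend on the prior count and measure no size, since a group had 0 counts for Runx2os1 and Arhgap15 and 3 for Blnk. For Runx2os1 and Blnk the control males were the group apart, and for Arhgap15 the Dnmt3l males. These values are per assembled transcript and were not summed by gene. Transcripts of a gene can differ in opposite ways between groups. The Adrb1 transcript TCONS_00280880 had 59.2 CPM in control males and 0 in control females, and TCONS_00280882 had 0.619 and 52.0. Whether the division of reads between transcripts gave the 3 calls was not tested. The fitted value for miR-7019-3p, listed at 0 in Dnmt3l males alone, was −8.61 and measures no size either. With the preset correlation camera called 15 gene lists, and 0 with an estimated correlation (adjusted p 0.391 to 0.847). Higher in males than females, as median differences, were clustered protocadherins 0.28, astrocytes 0.33, striatum 0.68, glucocorticoid-induced genes 0.24, mitochondrial mRNAs 0.60, microglia 0.33, endothelial cells 0.35, glutamate receptors 0.23, GABA receptors 0.23, postsynaptic genes 0.14, mature oligodendrocytes 0.23 and presynaptic genes 0.09. Lower were choroid plexus −1.32, heat-shock genes −0.40 and thalamus and hippocampus −0.71. The female effect in these tests includes DF1.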

How the results depend on the processing

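Of the alternatives below, limma on log2(scaled count + 1), edgeR's own low-count filter, microRNAs above 0 in all 12 libraries and the fits without CM3, CF1 and CF2 were chosen after the results were seen. The fit that the design named for normalized values, limma on log2(FPKM + 0.1), was added to the alternatives at that point too. All 3276 values of named features with 1 library left out kept their direction but 2, and 382 lost and 36 gained their call. Under the other settings 3177 values kept their direction but 7, with 350 calls lost and 125 gained. Gene lists lost 7 and gained 10 calls of 360 with a library left out. The 10 GO terms named for the averaged effect kept their calls in all 120 fits with a library left out, and all 10 lost them with an estimated correlation. For the values that moved, the cause was not tested, except that fits without the liver-holding controls, of 6 libraries or with stricter filters test with fewer libraries or features. At these depths and this spread 7.46%, 34.3% and 2.99% of simulated 2-fold changes were recovered for long non-coding, micro- and circular RNAs. There 35 of 72 long non-coding calls by DESeq2 were false (48.6%).

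With 1 library left out, Mup7 and Mup22 ran from −9.93 and −9.93 (without DM2) to 2.76 and 1.08 (without CM3) in males, reversing without CM3. Without CM3, CF1 and CF2 the averaged changes of Mup3, Ahsg, Mup7 and Mup22 were 0.98, 0.98, 3.01 and 2.35, the male changes of Mup7 and Mup22 2.74 and 1.07, and the female change of Alb 0.67. Calls without those 3 libraries were 4359 mRNAs averaged over sexes, 3684 in males, 2 in females, 1 for the difference and 0 for sex in controls, 6, 7 and 1 long non-coding transcripts (averaged, males, females), and 3, 2 and 1 circular RNAs (averaged, females, difference).

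Leaving out each library in turn, mRNA calls ran from 7203 to 9927 averaged over sexes, 5008 to 8431 in males, 7 to 7443 in females, 0 to 26 for the difference and 4 to 5 for sex in controls. The Dnmt3l change ran from 9.47 to 11.28 and the called gene lists from 10 to 14. Long non-coding calls ran from 27 to 177, 9 to 59, 0 to 11 and 0 to 4 (averaged, males, females, difference), microRNA calls from 5 to 121, 4 to 54, 1 to 49 and 1 to 11, and circular RNA calls from 3 to 33, 2 to 5, 1 to 37 and 0 to 3.

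For mRNA in females limma on log2(FPKM + 1) gave 375 calls, on log2(FPKM + 0.01) 277 and on log2(FPKM + 0.1) 339, quantile scaling 168, library weights 4597, the 6 female libraries 2 and DESeq2 3221, and DESeq2 called 5 for the difference. No gene list was called with an estimated correlation (0 of 30). For long non-coding RNA limma on log2(FPKM + 1) gave 97 averaged, 39 in males and 6 in females. With 0.01 added it gave 55 in males, 12 in females and 0 for the difference, and with 0.1 added 59, 6 and 0. In the order averaged, males, females, difference DESeq2 gave 554, 449, 136 and 72. Males, females and difference were 43, 7 and 1 with quantile scaling and 69, 5 and 0 with library weights. Males had 44 calls with no filter and 52 with the 6 male libraries. edgeR's own filter gave 111 averaged, 49 in males and 0 for the difference.

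For microRNA, in the order averaged, males, females, difference, no filter gave 82, 78, 46 and 26, DESeq2 73, 53, 22 and 19, library weights 173, 76, 67 and 7, quantile scaling 43, 32, 1 and 3, limma on log2(scaled count + 0.1) 65, 45, 10 and 4 and on log2(scaled count + 1) 59, 43, 10 and 4. With 10 added limma gave 44 averaged, 33 in males and 4 for the difference. A stricter filter gave 11 averaged, microRNAs above 0 in all 12 libraries 12 averaged and 0 for the difference, and the 6 male libraries 52 in males. For circular RNA, no filter gave 13 averaged, 6 in males and 4 for the difference, and the smallest value as pseudocount 9, 5 and 2. A pseudocount of 0.1 times that value gave 3 averaged and 0 in females, and a stricter filter 0 in males and 1 in females. Median-of-ratios scaling gave 3 averaged and 2 in females, quantile scaling 9 averaged, 5 in males and 2 in females, library weights 8 averaged and 10 in females, and the 6 female libraries 2.

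Samples of a number did not pair across groups: 0 of 18 pairs with the same number correlated above 0.1 (−0.335 to 0.0824), and 1 of 12 libraries correlated best with its own number. With the replicate number as a block, mRNA calls were 7893 averaged, 6498 in males and 1194 in females, long non-coding calls 30 averaged, 9 in males and 0 for the difference, and circular RNA calls in females 2, and 14 gene lists were called. MicroRNA columns bear the names of the longer-RNA libraries, numbers included, and were assigned to groups only, so the block planned for them was not run.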

Other observations

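Several genes displaced in all 6 Dnmt3l libraries are given here as examples, chosen after their values were seen and not as a theme of the set. Tlr5 and Tlr7, receptors of bacterial flagellin and of single-stranded RNA, Cd86, a costimulatory molecule, Fcrls, a microglial Fc receptor-like gene, and Alox5, the enzyme that starts leukotriene synthesis, were higher, with log2 changes averaged over sexes of 1.41, 0.87, 0.92, 1.06 and 1.49 (edgeR adjusted p 0.000162 to 0.00953). Maob, which degrades monoamines, Calb2 and Ppp1r1b, the dopamine-regulated phosphatase inhibitor, were lower, at −1.08, −1.24 and −1.17, as were Fdps, an enzyme of isoprenoid synthesis (−0.70), and Phyh, a peroxisomal enzyme (−1.16). Microglia express Fcrls, Tlr7 and Cd86, and the median log2 change of the microglial list was 0.72 averaged over sexes and −0.0289 in DF1.

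The noradrenaline receptors Adra1d, Adra1b and Adra1a rose by 0.44, 0.31 and 0.24 (edgeR adjusted p 0.00783, 0.00979 and 0.0171), and Adra1a was not called without CM2 or CM3 (0.0609 and 0.0728). Among autism and neurodevelopmental risk genes Dscam, a neuronal adhesion gene, and Shank3 rose by 0.41 and 0.51, and Ube3a, the Angelman syndrome ubiquitin ligase, fell by 0.52. Of the markers of red blood cells, Hba-a2, Hbb-bt and Hbb-bs had log2 changes of −1.11, −1.19 and −0.99. The list's medians were −1.64 in DF1, −1.42, −1.31 and −0.987 in DM1 to DM3, and −0.298 and −0.353 in DF2 and DF3. In males the GO term for the external side of the plasma membrane held 69 genes called higher and 3 lower (median 0.57, camera adjusted p = 1.38e-09, and adjusted p = 0.643 with an estimated correlation). In the difference between sexes homophilic cell adhesion was higher (0.23, camera adjusted p = 2.69e-06, and adjusted p = 0.871 with an estimated correlation).

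The tests by other splits of the libraries were chosen after the counts were seen. Of 200 possible splits of the 12 libraries 100 were run. Among these the real one alone gave as many mRNA calls averaged over sexes (1 of 100). It gave 8136 calls, against 7800 with DF1 and CF2 exchanged and 7607 with DF1 and CF3 exchanged. Since not all splits were run, a larger count in another is not excluded. Counts that high with DF1 among the controls point to a structure of the samples. For long non-coding RNA the real split also had the largest count of those run (63 against 12, 1 of 100). Few splits gave as many calls as the real one for microRNA (20 against 104, 2 of 100) and circular RNA (5 against 7, 4 of 100). There another split gave more calls than the real one, so the splits do not exclude chance. A split with 104 microRNAs, several times the real count, points to a structure of the samples as well. For the difference between sexes chance cannot be excluded for long non-coding RNA (3 against 8, 9 of 50) and microRNA (1 against 4, 21 of 50). For mRNA (0 against 4, 50 of 50) and circular RNA (0 against 2, 50 of 50) every split gives at least 0, so the splits decide nothing. Within a sex 10 splits are too few for a share under 0.05. Real and highest other counts there were, in males and females, 6802 against 0 and 1437 against 0 for mRNA, 18 against 1 and 0 against 1 for long non-coding RNA, 5 against 0 and 2 against 1 for microRNA and 3 against 3 and 4 against 5 for circular RNA, and 4 against 40 for sex in controls. The real split had the largest count for mRNA and microRNA in both sexes and for long non-coding RNA in males (1 of 10), while as many or more came from 10 of 10 for long non-coding RNA in females and from 2 of 10 for circular RNA in each sex and for sex in controls.

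Several microRNAs were listed at 0 in all controls and in DFa. miR-5126 had 7.33, 7.97 and 7.03 CPM in DMa to DMc and 8.86 and 4.68 in DFb and DFc, miR-6481 12.1, 23.8, 20.5, 40.1 and 13.4, and predicted microRNA 771 491, 389, 444, 328 and 363. Their edgeR adjusted p were 0.0428, 0.0456 and 0.0409. miR-99b-5p was listed at 0 in all controls, DFa and DFc and at 37663 to 42217 counts in the other 4 libraries. The log2 change of mRNAs averaged over sexes had a Spearman correlation of 0.0894 with gene length over 15786 genes. The 10 most abundant genes took 4.46% to 5.22% of counts in controls, 5.53% in DF1 and 7.97% to 10.1% in the other 5 Dnmt3l libraries. Library weights were 0.150 in DF1 and 0.789 to 1.99 in the other 11 libraries.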
